A study of Rattus norvegicus with 3 samples.

How the data were processed

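RNA from peripheral blood mononuclear cells of 2-month-old male Sprague-Dawley rats was hybridised to the Affymetrix Rat Expression Array 230 2.0, a 3' expression array with several probe sets for many genes. The labels assign 1 array each to a control group, a downhill treadmill running group and an uphill treadmill running group. Per the labels' protocols, cells were taken from 2 ml of a mixture and labelled with biotin by the manufacturer's standard procedure. The makeup of that mixture, the number of rats behind each array, the length and number of running bouts and the time of blood sampling are not given in the sources used here.

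The deposited matrix holds an intensity for each of 31099 probe sets on each array, normalized by the authors with RMA, a method of background correction, quantile normalization and probe set summary, per the submitters' processing notes. The software and its version are not given in the sources used here. The deposited intensity values are on a linear scale from 1 to 34067, not on the log2 scale that RMA usually gives and that the analysis plan had assumed, and their distributions are not identical across arrays, so a further scaling by the authors is possible but not recorded. The deposited matrix also holds a present, marginal or absent call per probe set, whose algorithm is not stated, and annotation with alignments to the Rnor3.4 assembly. A separate deposited value table held the same intensity in all 93297 cells within 1e-06 and was not used further.

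Intensity values were converted to log2 here, without an offset (39 values equal 1). Of the probe sets, 19628 carried exactly 1 gene symbol, 800 carried several and 10671 carried none, and 57 were controls. Symbols were updated through Entrez numbers to the current rat gene table (assembly GRCr8, names only), in which 19192 probe sets matched and 2091 changed name. The probe set with the highest mean over the 3 arrays stood for a gene with several, which left 13893 genes, 4065 of them with several probe sets. A gene was counted in a comparison where the brighter of the 2 arrays reached 353, the median of all gene values. Folds are ratios of intensity, written as "at least" where the dimmer array was not called present, since its value is then background, and left out where the brighter array was not called present.

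With 1 array per group no test was possible, and a gene was counted where it differed by at least 2-fold. The text names the 12 genes with the largest difference each way for each running array against control, the 8 largest each way for downhill against uphill, and up to 4 members of each gene list, a rule set before the data were examined. Some genes that meet the rule are not reported here. Exceptions are said in the text to be named after their values were seen.

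There were 28 gene lists, 12 of cell type markers and 16 of pathways, also set before the data were examined. For each list with at least 5 members above the floor, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list outside the central 95% is said to stand apart. Random lists treat genes as independent while genes of 1 pathway move together, so this describes the arrays and is not a test. This left 25 lists, since the dendritic cell list had 4 detected members, the basophil and mast cell list 2 and the hepatocyte list 0. Of the list members on the array, 9 glucocorticoid, 6 monocyte and 5 immediate early genes also stand in another list.

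The script was tested on simulated data made from the real genes, with 200 of 7383 genes changed in a simulated downhill against control comparison and noise drawn from the differences between downhill and uphill. In this 1 draw it counted 10.4% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 100% of those changed 4-fold. It also counted 0.640% of unchanged genes. Over 100 draws without changes, means of 33.7 genes higher and 34.3 lower of 7410 were counted, a larger share. Simulated correlations with a shared control used 100 draws of the same noise, which also holds any real difference between the runs. Precision is limited by the number of arrays. For 1061 genes with another probe set above the floor, the probe sets differed by a median of 0.14 (downhill against control), 0.19 (uphill against control) and 0.18 (downhill against uphill) on the log2 scale, with 95th percentiles of 0.56, 0.66 and 0.60. Of the 8, 10 and 5 such genes that differed 2-fold by the brightest probe set, the other probe set differed at least 1.5-fold the same way for 6, 6 and 2. Spike-in controls of E. coli added to each sample differed by a median of 0.27 between downhill and control and 0.11 between uphill and control, those of B. subtilis by -0.21 and -0.17, and those of phage P1 by 0.091 and 0.089.

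Alternatives set beforehand were a 1.5-fold threshold, no floor, a floor at the 75th percentile (964), cyclic loess on the log2 values (span 0.7, 3 iterations), centring on the median, the mean of a gene's probe sets, and the mean in place of the median of a list. A filter on present calls and lists without shared genes were added after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3 with limma 3.58.1.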

Results

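The series measured gene expression in peripheral blood mononuclear cells, the lymphocytes and monocytes of blood, from young male Sprague-Dawley rats. It asked how uphill and downhill treadmill running, which load muscle mainly through shortening and lengthening contractions respectively, alter the mRNA profile of these cells. There were 3 arrays, 1 from control rats, 1 from the downhill group and 1 from the uphill group. With 1 array per group there was no replicate spread, so no difference below has a p-value and each one compares these arrays rather than the conditions. The median intensity over 31099 probe sets was 228.74 on the control array, 219.29 on the downhill array and 216.51 on the uphill array, and 53.7%, 52.4% and 54.4% of probe sets were called present. The ratio of the 3' to the 5' actin probe set, a measure of RNA and labelling quality, was 2.39, 2.87 and 2.68 in that order. For GAPDH this ratio was 1.18, 1.20 and 1.32.

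The downhill array was first compared with the control array, which asks what the blood cells of downhill runners express differently. Gpnmb, a membrane glycoprotein of macrophages, had the largest difference upward and was 7.09-fold higher (intensity 1755 against 247.63). The lectin Fcnb was 5.42-fold higher, the matrix proteoglycan Vcan 4.50-fold, the monocyte chemokine Ccl2 4.17-fold, the complement component C2 3.76-fold and the lectin receptor Clec10a 3.68-fold. Pglyrp1, a bactericidal granule protein, had the largest difference downward and was 6.09-fold lower (205.97 against 1254), the decoy interleukin-1 receptor Il1r2 was 4.11-fold lower, and the prostaglandin synthase Ptgs2 and the chemokine Cxcl2 were 5.13-fold and 3.33-fold lower.

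Of 7265 genes bright enough to be counted, 60 were at least 2-fold higher and 20 at least 2-fold lower on the downhill array. Over the 7410 genes bright enough on any of the 3 arrays the counts were also 60 and 20. In simulated arrays of those 7410 genes without changes, whose noise was drawn from the differences between the downhill and uphill arrays, 33.7 genes (95% of simulations 23.5 to 44.5) were higher and 34.3 (25 to 45) lower by this rule. The observed 60 higher lay above its simulated range and the observed 20 lower lay below its range. That noise also holds any real difference between the runs, so the ranges are no clean measure of noise. The other genes with the largest differences were Rnase2 (6.46-fold higher), Thbd (4.12-fold), Tubb6 (4.08-fold), the urea cycle enzyme Ass1 (3.66-fold) and Tppp3 (at least 3.52-fold). On the lower side they were the triglyceride synthesis enzyme Dgat2 (3.0-fold), the metalloproteinase Mmp9 (at least 2.78-fold), the cytokine Tnf (2.69-fold), the histamine-forming enzyme Hdc (2.68-fold), Retnla (2.57-fold), S100a8 (2.45-fold), the antimicrobial peptide Camp (2.25-fold) and the neutrophil collagenase Mmp8 (2.24-fold). Other probe sets of the same gene differed for 3 of these. The log2 difference of the other Tubb6 probe set was 0.07, that of the other Tnf probe set was -0.12, and the other Thbd probe sets gave 0.26 to 1.87, whereas the 4 other Vcan probe sets gave 2.11 to 2.29. On the Rnor3.4 assembly, Gpnmb aligned to chromosome 4 (77161351 to 77182624, plus strand), Vcan to chromosome 2 (19714327 to 19812494, minus strand) and Pglyrp1 to chromosome 1 (78235473 to 78240704, plus strand).

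Among the cell type markers, the monocyte list had a median log2 difference of 0.65 between downhill and control, above all 10000 random lists of matched brightness, with 17 of 19 members higher. The members that differed most included Vcan (2.17), the endotoxin co-receptor Cd14 (1.71) and the ficolin Fcna (1.25). The neutrophil list had a median of -1.14, below all 10000 random lists, with 8 of 11 members lower. Il1r2 (-2.04), Mmp9 (-1.48, absent on the downhill array), S100a8 (-1.29) and Camp (-1.17) differed most, but 3 members named after their values were seen went the other way, with Slpi at 1.10, Hp at 0.59 and Chi3l1 at 0.24. Of 13 detected genes of an additional neutrophil list, drawn up after this difference had been seen, 8 were higher and the median was 0.069, inside the central 95% of random lists (-0.18 to 0.17). Natural killer and cytotoxic lymphocyte genes had a median of 0.24 with 15 of 16 members higher, among them Cst7 (0.73), Cd244l1 (0.69), Gzmb (0.45) and Il2rb (0.45).

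Platelet genes had a median of -0.30 on the downhill array with 15 of 17 lower, and B cell genes a median of -0.23 with 10 of 13 lower. Platelet receptor genes P2ry12 (-0.69) and Gp5 (-0.60) were lower and Tbxas1, a thromboxane synthase, was higher (1.03). In the B cell list Cd79b was lower (-0.36) and Ms4a1 higher (0.33). The mean of the B cell members, -0.13, lay inside the random lists. The erythroid list had a median of -0.18, at percentile 2.38 of the random lists and inside them without the filter on dim genes (-0.075) or as a mean (-0.15). The T cell list (median -0.10, 17 genes), the plasma cell list (-0.0099, 7 genes) and the skeletal muscle list (-0.14, 6 genes) lay inside the central 95% of random lists.

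Among the pathway lists, genes of protein breakdown and of mitochondrial respiration were higher on the downhill array. The proteasome and ubiquitin list had a median of 0.27 (31 of 35 members higher), with Psmb3 at 0.47, Psmd7 at 0.46 and Psma4 at 0.45. The nuclear-coded oxidative phosphorylation list had a median of 0.29 (59 of 62 higher), with Ndufv2 at 0.71, Sdhb at 0.70, Ndufa5 at 0.58 and Atp5po at 0.58. Each of these medians lay above all 10000 random lists. They were close in size to the median difference of the E. coli spike-in controls between the same arrays (0.27), while the B. subtilis controls gave -0.21. The fatty acid oxidation list had a median of 0.14 (25 of 29 higher), led by the lipid droplet protein Plin2 (1.61) and the fatty acid transporter Cd36 (0.69). MHC class II presentation had a median of 0.24 (9 of 9 higher), led by Ifi30 (0.80) and Ctss (0.56), which is also in the monocyte list. Its members Cd74 (0.0080) and Ciita (0.015), named after their values were seen, hardly differed. The ribosomal protein list had a small median of 0.093 (33 of 35 higher), which was inside the random lists without the filter on dim genes and in both settings that took means.

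The remaining pathway lists stayed inside the central 95% of random lists between downhill and control. Their medians were 0.088 for the type I interferon response, -0.10 for inflammatory cytokines and NF-kB targets, -0.054 for immediate early genes, -0.018 for heat shock proteins, 0.095 for glucocorticoid-responsive genes and 0.054 for glycolysis and hypoxia targets. They were -0.0030 for antioxidant and NRF2 targets, -0.025 for the cell cycle, 0.028 for Toll-like receptor signalling, -0.099 for apoptosis and p53 targets and 0.16 for matrix and tissue repair genes, a list that stood apart under 4 alternatives (0.23 to 0.68). Members could still differ widely. In the cytokine list Ptgs2 was at -2.36 and Cxcl2 at -1.73 while Ccl2 was at 2.06 and the urokinase receptor Plaur at 1.47. In the glucocorticoid list Il1r2 was at -2.04 while Thbd was at 2.04 and the metallothioneins Mt2A and Mt1 at 1.71 and 1.23. In all, 7 of 25 lists stood apart from the random lists on the higher side and 4 on the lower side. If genes were independent, 1.25 lists would be due by chance in total. Genes of 1 pathway move together, so that figure is no fair yardstick.

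**Figure D1:**
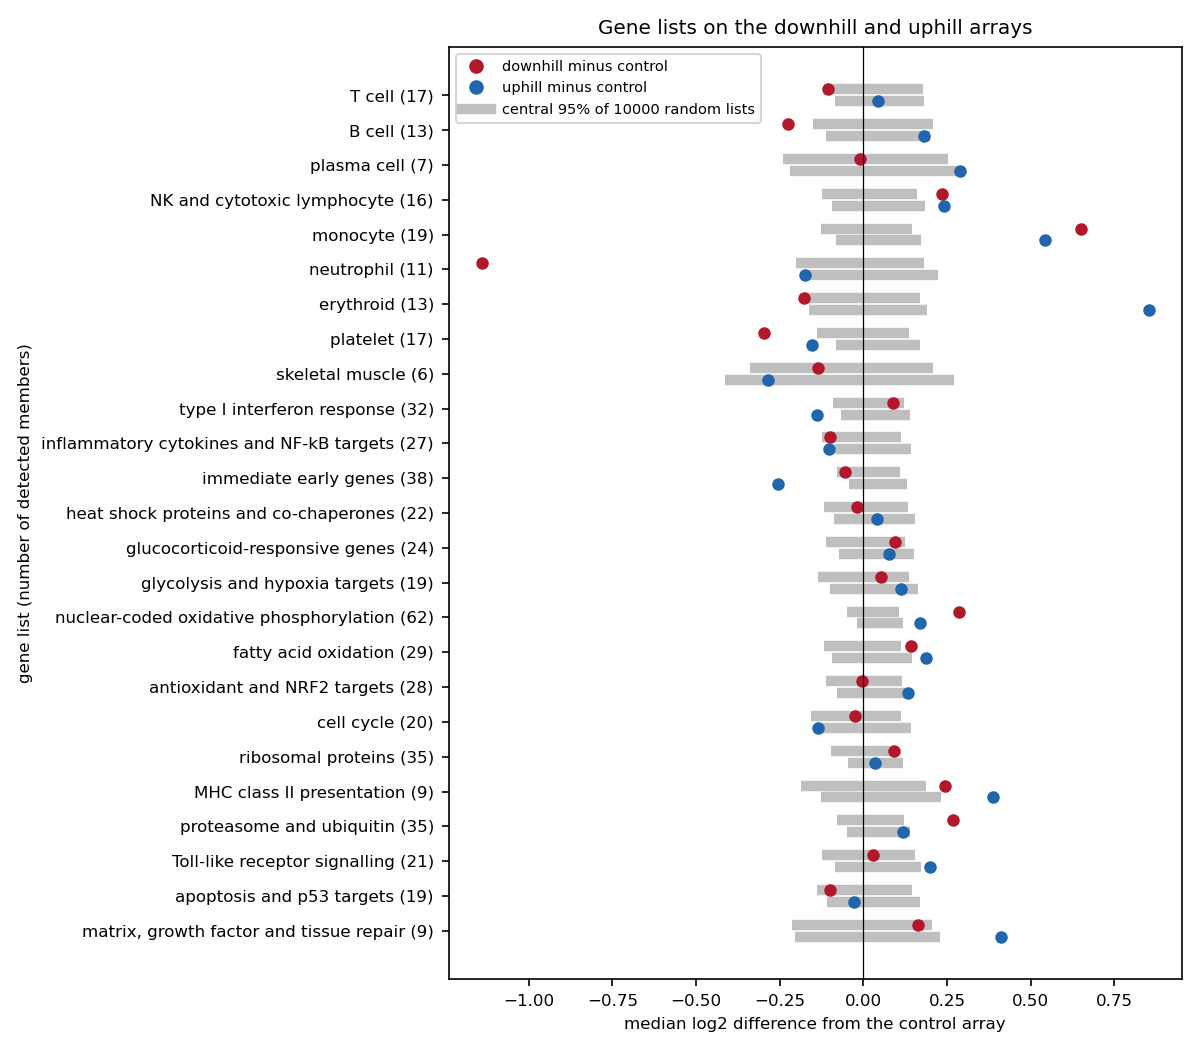
Median log2 difference from the control array of the detected members of 25 gene lists, for the downhill array (red points) and the uphill array (blue points); the number of detected members is in brackets and grey bars span the central 95% of 10000 random lists of the same size and brightness. The monocyte list lay to the right of its bars on both arrays (0.65 and 0.54), the neutrophil list far to the left on the downhill array (-1.14) and the erythroid list far to the right on the uphill array (0.85).

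The uphill array was compared with the control array to ask the same question for uphill running. The largest differences upward included globin genes. Hbq1b was at least 12.6-fold higher (4380 against 346.27) and Hba-a3 at least 7.69-fold. Fech, the last enzyme of haem synthesis, was 6.61-fold higher, Tmcc2 6.46-fold and Selenbp1 at least 5.31-fold. The antiviral gene Rsad2 was 6.54-fold higher. Of the immediate early list, the AP-1 subunit Fosb was 5.85-fold lower, the stress transcription factor Atf3 2.54-fold and the AP-1 subunit Jun 2.48-fold. Of the cytokine list, Ptgs2 was 6.01-fold lower, Tnf 3.05-fold and the chemokine Ccl4 2.57-fold, and Hdc, of neither list, was 4.64-fold lower.

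Of 7320 genes, 61 were at least 2-fold higher and 34 at least 2-fold lower on the uphill array. Over the 7410 genes bright enough on any array the counts were 62 and 34. Simulated unchanged arrays, counted for downhill against control, gave 33.7 higher (23.5 to 44.5) and 34.3 lower (25 to 45). The 34 lower genes lay inside that range. The simulated noise came from the differences between the downhill and uphill arrays, which hold any real uphill difference. The range therefore cannot say whether the 34 genes exceed noise. Gpnmb (5.08-fold), Tldc2 (4.28-fold), Pgrmc2 (4.18-fold) and Vcan (3.82-fold) were also among the 12 genes with the largest differences upward. The nuclease Dnase2b (5.19-fold), G0s2, an inhibitor of lipolysis (3.72-fold) and the mast cell protease Mcpt9 (2.59-fold) were also among the 12 lowest. The embryonic globin Hbe1 (log2 difference 3.11), Nr2e3 (2.64) and Fam221b (-1.33) met the rule on size but were not called present on the brighter array, so no fold is given for them. The other Pgrmc2 probe sets gave log2 differences of -0.00062 to 0.19 and the other Tnf probe set -0.40. The Jun probe set can bind related transcripts, and the other Jun probe sets gave -2.14 and -2.10. On Rnor3.4, Hbq1b aligned to chromosome 10 (15581390 to 15582086, minus strand), Fech to chromosome 18 (60675974 to 60677468, minus strand), Rsad2 to chromosome 6 (44100772 to 44113910, minus strand) and Fosb to chromosome 1 (78666419 to 78666858, minus strand).

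The erythroid list had a median log2 difference of 0.85 between uphill and control, above all 10000 random lists, with 10 of 13 members higher. The members that differed most included Fech (2.73), the red cell enzyme Bpgm (1.84) and the alpha globin chaperone Ahsp (1.68, absent on the control array). The blood group protein Rhag (-0.28), the transferrin receptor Tfrc (-0.093) and Gypc (-0.32), named after their values were seen, were not higher. The 5 probe sets that match several haemoglobin genes, which entered no list, had a median of 3.11 (2.37 to 3.83), against -0.63 to -0.44 on the downhill array, and the brightest of them was the brightest probe set of the uphill array at 33326. An additional erythroid list of 28 detected genes, drawn up after this difference had been seen, had a median of 0.087, inside the random lists (-0.077 to 0.14).

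The monocyte list had a median of 0.54 on the uphill array, above all 10000 random lists, with 18 of 19 members higher. Vcan (1.93), Cd14 (1.53) and Fcna (0.79) were higher and the nuclear receptor Nr4a1, which is also in the immediate early list, was lower (-1.05). Natural killer and cytotoxic lymphocyte genes had a median of 0.24 (14 of 16 higher), with Cd244l1 at 0.50, Il2rb at 0.49, Klrb1b at 0.47 and the receptor Ncr1 at -0.49. Platelet genes had a median of -0.15 (14 of 17 lower), with P2ry12 at -0.55, Gp5 at -0.46 and Tbxas1 at 0.97. Plasma cell genes had a median of 0.29 over 7 genes, with Xbp1 at 0.62 and Sdc1 at 0.34, and were inside the random lists under 4 alternatives. The neutrophil list had a median of -0.18 at percentile 1.83 of the random lists, with 6 of 11 members lower and Hp at 1.39, while the mean of its members was 0.021. The additional neutrophil list went the other way on this array, with a median of 0.30 at percentile 99.8 and 9 of 13 members higher. B cell (median 0.18, 13 of 13 higher), T cell (0.043) and skeletal muscle genes (-0.28) lay inside the random lists.

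The immediate early list had a median of -0.25 on the uphill array, below all 10000 random lists, with 31 of 38 members lower. Fosb (-2.55), Atf3 (-1.35), Jun (-1.31) and Nr4a1 (-1.05) differed most. The inflammatory cytokine list had a median of -0.10 (17 of 27 lower, percentile 1.15), led by Ptgs2 (-2.59), Tnf (-1.61), Ccl4 (-1.36) and Cxcl2 (-1.05), and lay inside the random lists without the filter on dim genes (-0.079). The type I interferon list had a median of -0.14 (22 of 32 lower), with Ifit2 at -0.93 and Isg15 at -0.82. Rsad2 (2.71) and Ifih1 (1.54) were the members that differed most and were higher, although Ifih1 was called absent on every array. The mean of the interferon members, -0.042, lay inside the random lists.

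Higher on the uphill array were MHC class II presentation (median 0.39, 8 of 9 members), oxidative phosphorylation (0.17, 55 of 62), fatty acid oxidation (0.19, 24 of 29), Toll-like receptor signalling (0.20, 16 of 21) and matrix and tissue repair genes (0.41, 5 of 9). Ifi30 (0.83) and Ctss (0.62) led the first, Uqcr11 (0.66) and Uqcrc1 (0.59) the respiratory chain, Cd36 (1.18) and Acsl5 (0.77) fatty acid oxidation, Cd14 (1.53) and Tlr8 (0.50) the Toll-like receptor list, and Fn1 (1.87) and Tgfbi (1.49) the matrix list. The matrix list was split, with 3 members at least 1.5-fold higher and 3 at least 1.5-fold lower. Its median was -0.014 without the filter on dim genes and lay inside the random lists with the mean of a gene's probe sets. Medians inside the central 95% of random lists were 0.041 for heat shock proteins, 0.077 for glucocorticoid-responsive genes, 0.11 for glycolysis and hypoxia targets, 0.13 for antioxidant and NRF2 targets, -0.14 for the cell cycle, 0.035 for ribosomal proteins, 0.12 for proteasome and ubiquitin and -0.029 for apoptosis and p53 targets. In all, 9 lists stood apart on the higher side and 5 on the lower side.

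**Figure D2:**
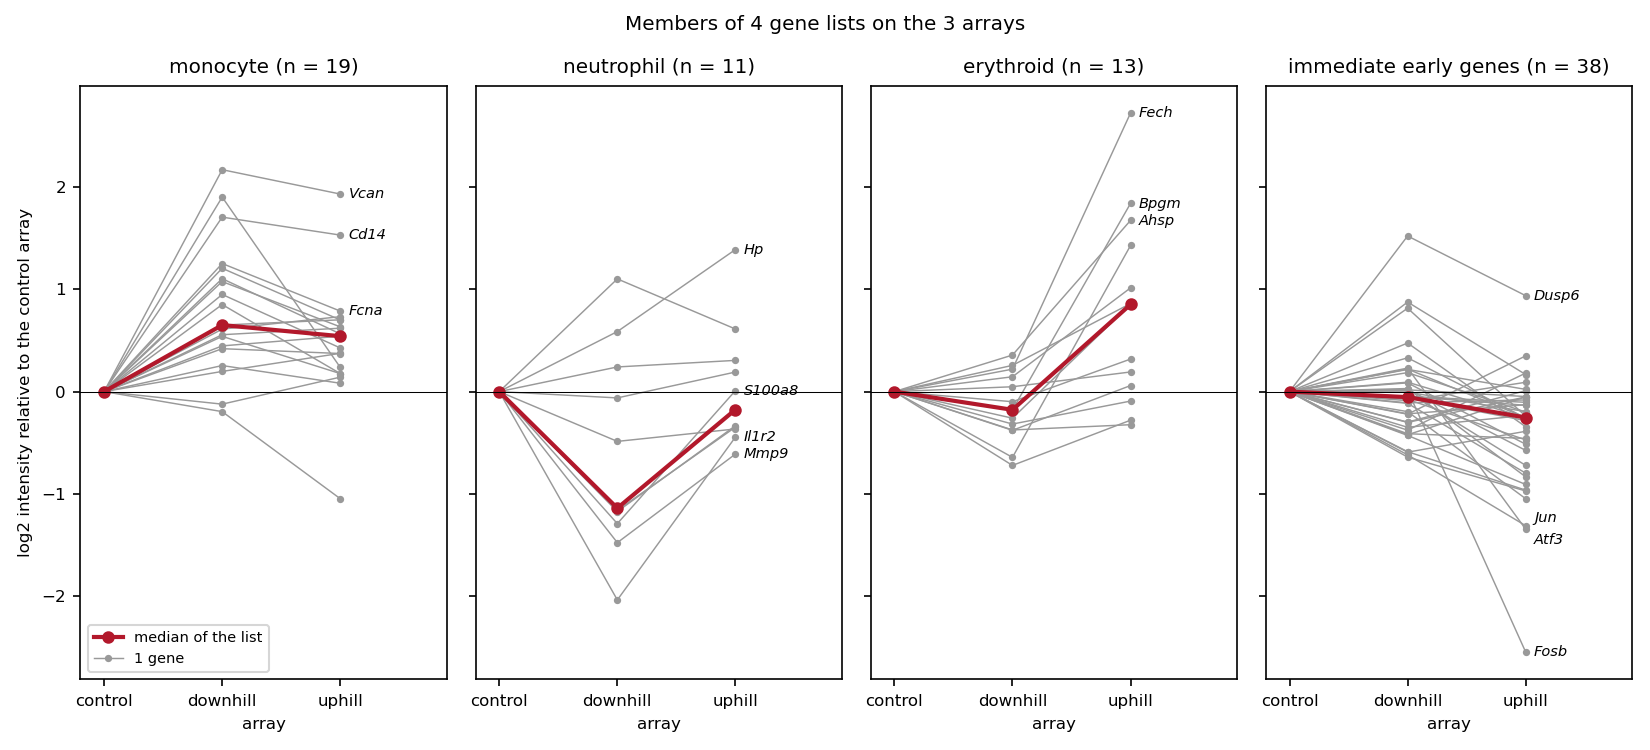
Log2 intensity relative to the control array of each detected member (grey lines, 1 per gene) and the median (red line) of the monocyte, neutrophil, erythroid and immediate early lists on the control, downhill and uphill arrays, with some of the members that differed most named. Monocyte genes were higher on both running arrays (medians 0.65 and 0.54), neutrophil genes were lowest on the downhill array (-1.14), erythroid genes highest on the uphill array (0.85) and immediate early genes lowest on the uphill array (-0.25).

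The downhill and uphill arrays were then compared directly, which asks whether the direction of the slope matters. The immediate early genes Fosb and Atf3 were 5.90-fold and 2.98-fold higher on the downhill array. Also higher there were the Notch target Hes1 (3.60-fold), G0s2 (3.17-fold), the thrombin receptor F2r (3.06-fold) and Rgcc (2.99-fold). Frmd4b was 3.01-fold higher, but its other probe set had a log2 difference of 0.20. Lower on the downhill array were the globin genes Hbq1b, at least 19.9-fold, and Hba-a3, at least 15.4-fold, with Rsad2 10.2-fold, Tmcc2 at least 7.44-fold, Selenbp1 at least 5.79-fold and Fech 5.68-fold. Of 7171 genes, 24 were at least 2-fold higher and 34 at least 2-fold lower on the downhill array. The simulated noise was drawn from this very difference, so it gives no separate figure to set beside these counts.

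Neutrophil genes were lower on the downhill than on the uphill array (median log2 difference -0.81, 10 of 11 members lower), as were erythroid genes (-0.61, 13 of 13) and B cell genes (-0.36, 12 of 13). The additional neutrophil and erythroid lists lay inside the random lists in this comparison, with medians of 0.039 (7 of 13 higher) and -0.11 (11 of 28 higher). Immediate early genes (0.36, 28 of 38 higher), monocyte genes (0.24, 13 of 19), proteasome and ubiquitin genes (0.18, 26 of 35), type I interferon genes (0.18, 22 of 32) and oxidative phosphorylation genes (0.11, 43 of 62) were higher on the downhill array. Fosb (2.56) and Atf3 (1.58) led the immediate early list. The mean of the interferon members, 0.085, lay inside the random lists, and the member that differed most, Rsad2 (-3.35), went the other way. Ribosomal protein genes stood apart on the higher side with a median of 0.027 (20 of 35 higher), although the mean of their members was -0.025. The other 16 lists lay inside the random lists, with medians from -0.14 for platelet and T cell genes to 0.056 for natural killer and cytotoxic lymphocyte genes.

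The downhill and uphill differences from the control were also set against each other. Across 7410 genes they had a Pearson correlation of 0.55 and a Spearman correlation of 0.55, genes not being independent replicates. Gpnmb, Rnase2, Fcnb, Vcan, Thbd, Tubb6, C2, Clec10a and Ass1 were among the 20 genes at least 2-fold higher on both running arrays. Ptgs2, Tnf, Cxcl2, Hdc and Dnase2b were the 5 genes at least 2-fold lower on both. The other Tubb6 probe set gave 0.07 on the downhill array, and the other Tnf probe set -0.12 (downhill) and -0.40 (uphill). Ptgs2 reached the floor only on the control array. Both differences share the control array, which alone gives a positive correlation. Simulated unchanged arrays against that control gave a correlation of 0.50 (0.46 to 0.54), 11.5 genes higher on both (5 to 19) and 15.5 lower on both (10 to 23), while independent lists would share 0.502 and 0.0918 genes. The covariance was 0.0595 against 0.0489 in the simulation (0.0440 to 0.0551), a difference of 0.0106. The single control array cannot be split, so part or all of the excess may come from it. The 20 genes higher on both lay just above the simulated range, whereas the 5 lower on both lay below theirs.

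**Figure D3:**
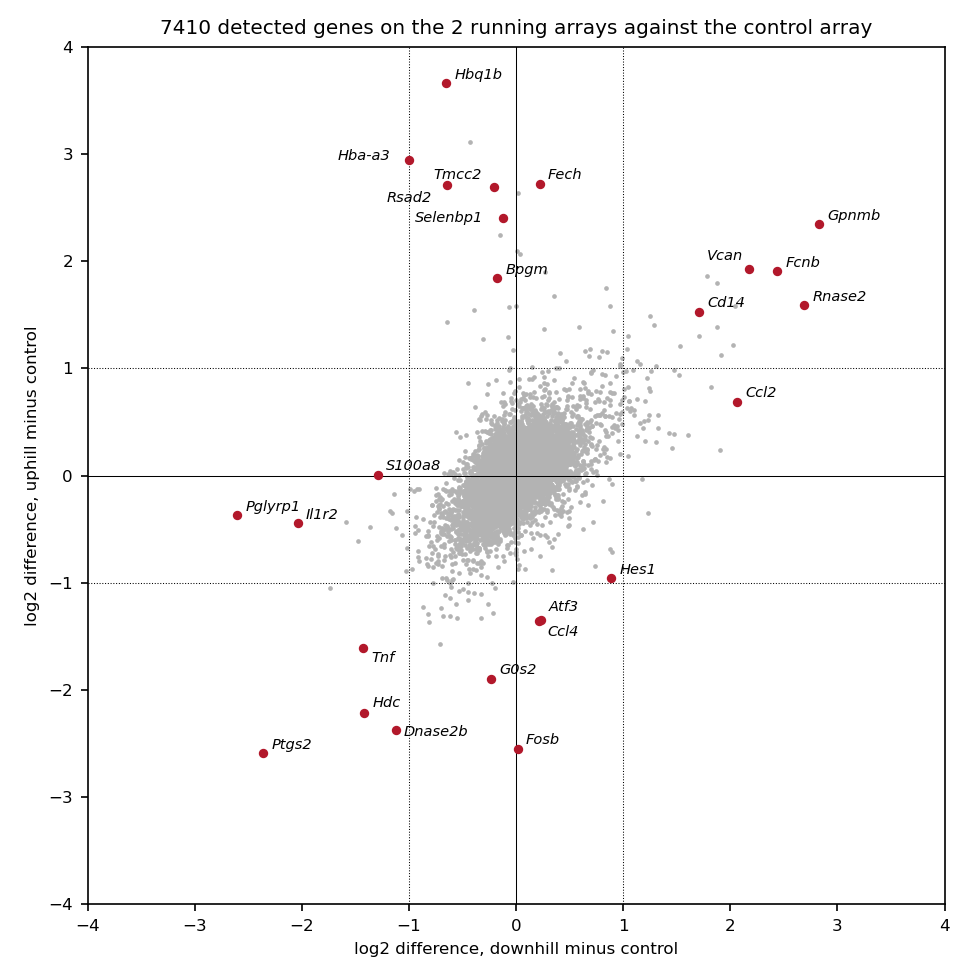
Log2 difference from the control array of 7410 genes (grey points, 1 per gene) on the downhill array (horizontal axis) and on the uphill array (vertical axis), with dotted lines at 2-fold and selected genes named in red. Gpnmb and Vcan lay far from 0 on both axes, Fech (2.73 uphill, 0.22 downhill) and Fosb (-2.55 uphill, 0.013 downhill) on the uphill axis, and Pglyrp1 (-2.61 downhill, -0.37 uphill) on the downhill axis.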

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

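The comparison of monocyte with T cell genes, the monocyte genes of no other list and the heat shock value were tests chosen only after the result they bear on had been seen. Cyclic loess, an alternative set beforehand, was taken as a test of these patterns only then. The random lists, matched on brightness, already allow for an intensity trend, so cyclic loess was a weak further check on it. Bootstrap intervals in the paragraphs below resample the genes of a list and hold no spread between samples. Neither the differences between the running arrays given here nor their directions were tested, since each group had 1 array. Several genes lay at least 1.5-fold above the control on 1 running array and at least 1.5-fold below it on the other. Higher on the downhill and lower on the uphill array were Hes1 (downhill minus uphill 1.85 on the log2 scale), F2r (1.61), Rgcc (1.58) and Mex3b (1.57, named after its value was seen). Rsad2 (-3.35) was lower on the downhill and higher on the uphill array. Hbq1b (-4.31) and Hba-a3 (-3.95) had the same signs, but both were called absent on the control and downhill arrays, so their lower value on the downhill array compares background and their differences are lower bounds in size. The 5 probe sets shared by haemoglobin genes, called present on all 3 arrays, were also lower on the downhill array (-0.63 to -0.44). The erythroid list had a downhill minus uphill median of -0.61. Its medians against the control had opposite signs, but that on the downhill array was only -0.18 with 5 of 13 members higher, and it lay inside the random lists without the filter on dim genes (-0.075) or as a mean (-0.15). Probe sets with no gene symbol or several, which entered no gene count or list, also differed from the control. At least 2-fold higher were 23 of 2920 on the downhill and 27 of 2967 on the uphill array, and 15 were at least 2-fold lower on each.

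Erythroid genes were higher on the uphill array, with a list median of 0.85. An intensity trend left by the normalization is argued against as the whole cause, because the median was 0.81 after cyclic loess, outside the random lists (-0.17 to 0.19). The 5 probe sets shared by haemoglobin genes, whose direction was predicted before their values were seen but after those of Hba-a3, Hbq1b and Hbe1, had a median of 3.11, consistent with more red cell RNA in the uphill sample, and they may be understated because they lie near the brightest signals. An additional erythroid list, written before its values were seen, had a median of 0.087 (bootstrap interval -0.14 to 0.30), so it neither added to nor excluded red cell precursors as the source. Carry-over of immature red cells into this 1 preparation and an effect of uphill running on circulating red cells both stay open as hypotheses, the effect of slope being untested.

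Neutrophil genes were lower and monocyte genes higher on the downhill array. After cyclic loess the neutrophil median was -1.13, outside the random lists (-0.20 to 0.18), which argues against an intensity trend as the whole cause. A loss of neutrophil RNA would raise monocyte and T cell genes alike. The monocyte median exceeded the T cell median by 0.76 (bootstrap interval over genes 0.52 to 1.22), both medians having been seen before. On these arrays this argues against that loss as the whole cause of the higher monocyte genes. Fewer neutrophils in the downhill sample could not be settled. The additional neutrophil list, written before its values were seen, had a median of 0.069 where a loss would put it below the random lists. As first written, the rule counted a median at or above that of the random lists (0.0005) against fewer neutrophils. The value of 0.069 met that rule. However, the list's bootstrap interval (-0.029 to 0.46) reached below that bound. The requirement that the interval clear the bound was set after this value was seen and turned the outcome to undecided. Different carry-over of neutrophils, lower expression of neutrophil genes such as S100a8 and Camp, and an untested effect of downhill running may each contribute.

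Immediate early genes were lower on the uphill array, with a list median of -0.25. The median was -0.30 after cyclic loess, outside the random lists (-0.085 to 0.092), which argues against an intensity trend as the whole cause. Fewer monocytes, which express many of these genes, are argued against on these arrays only. The 15 monocyte genes of no other list had a median of 0.54 (bootstrap interval over genes 0.24 to 0.70). That is also the median of the whole monocyte list, which had been seen before, so it is no separate test. Immediate early genes also respond within minutes to the handling of blood, and the heat shock list, with a median of 0.041 inside the random lists, decides nothing about that. With 1 array per group and no handling times, a difference in handling cannot be told apart from an effect of uphill running.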

How the results depend on the processing

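The filter on present calls and the lists without shared genes were added after the data were seen. There were no replicates to leave out, the separate value table was identical and gave no alternative value, and no paired analysis was possible because each group had 1 array. The counts of genes 2-fold higher and lower stayed within 1.5 times under cyclic loess, median centring, the mean of a gene's probe sets and present calls. The correlation between the runs was recomputed under cyclic loess, the mean of a gene's probe sets and no filter on dim genes. In these settings it stayed within its bootstrap interval over genes (0.52 to 0.59). By construction, the 1.5-fold threshold gave more genes: 242 higher and 170 lower (downhill against control), 240 and 225 (uphill against control), and 155 and 159 (downhill against uphill). Without the filter on dim genes 33 were lower on the downhill and 55 on the uphill array than on the control, and 42 were higher and 54 lower on the downhill than on the uphill array. With the floor at the 75th percentile these counts were 10, 13, 15 and 21, fewer genes being counted. Of 75 list medians, 71 kept their place inside or outside the random lists under cyclic loess, 68 without the filter, 65 with the mean of a gene's probe sets, 60 as means and 72 without shared genes. For the others the cause was not tested. Among medians that stood apart, the sign turned for the matrix list uphill (-0.014 without the filter), the neutrophil list uphill (0.021 as a mean, 0.0097 without shared genes) and the ribosomal list downhill against uphill (-0.025 as a mean). Medians inside the random lists turned sign too, among them T cell (-0.0053) and heat shock genes (-0.0032) uphill after loess, and muscle (0.11 without the filter) and cytokine genes (values given among those that came to stand apart) downhill against uphill. Medians that no longer stood apart were those of plasma cell genes uphill (0.14 without the filter, 0.25 after loess, 0.13 with the mean of probe sets, 0.21 as a mean), erythroid genes downhill (-0.075 without the filter, -0.15 as a mean), cytokine genes uphill (-0.079 without the filter), ribosomal genes downhill (0.093 without the filter, 0.099 with the mean of probe sets, 0.083 as a mean) and against uphill (0.027 without the filter), neutrophil genes uphill (-0.083 with the mean of probe sets), matrix genes uphill (0.13 with the mean of probe sets), B cell genes downhill (-0.13 as a mean), and interferon genes uphill (-0.042 as a mean) and downhill against uphill (0.085 as a mean). Medians that came to stand apart were those of cell cycle genes uphill (-0.16 without the filter, -0.15 after loess, -0.15 as a mean), antioxidant genes uphill (0.12 after loess, 0.15 without shared genes), matrix genes downhill (0.23 after loess, 0.24 with the mean of probe sets, 0.30 as a mean, 0.68 without shared genes), T cell genes downhill (-0.12 with the mean of probe sets), muscle genes uphill (-0.42 with the mean of probe sets), cytokine genes downhill (-0.11 with the mean of probe sets, -0.15 as a mean) and against uphill (0.15 and 0.14 in the same settings), glucocorticoid genes (0.12 downhill against uphill with the mean of probe sets, 0.17 uphill as a mean), and, as means, Toll-like receptor (0.22) and apoptosis genes (-0.16) downhill. Of 64 values of named genes, 60 stayed at least 2-fold with the mean of probe sets and 64 after loess; the exceptions included Tnf (-0.77 downhill), Pgrmc2 (0.75 uphill) and Frmd4b (0.89 downhill against uphill). Signal over background limits genes called absent. Spike-in controls differed in both directions between downhill and control, by medians of 0.27 (E. coli), 0.091 (phage P1) and -0.21 (B. subtilis).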

Other observations

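Of the 11 basophil and mast cell genes on the array only 2 were detected, too few for a place among random lists, and the values here were picked after they were seen. The histamine-forming enzyme Hdc had log2 differences of -1.42 (downhill) and -2.21 (uphill). The transcription factor Gata2, called absent on both running arrays, was at least 1.82-fold and 2.34-fold lower. The protease Mcpt9, which was in no list, was at -0.81 and -1.37. Below the floor on all 3 arrays, the IgE receptor subunit Fcer1a was at -0.98 and -1.43 (called marginal on the uphill array), Cpa3 was at -0.16 and -0.18, and the IgE receptor subunit Ms4a2 (called absent on the downhill array) was at -0.65 and -0.58. Counted without the filter on dim genes, 10 of the 11 list members were lower and 1 higher on each running array, Il13 (0.17) on the downhill and Tpsab1 (0.21) on the uphill array, but 6 of the 11, these included, were called absent on every array, so their signs compare background.

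Cfd, Fn1 and Tgfbi were also among the 20 genes at least 2-fold higher on both running arrays and are named here after their values were seen. The complement factor Cfd had log2 differences of 1.53 (downhill) and 1.21 (uphill), fibronectin (Fn1) 1.78 and 1.87, and Tgfbi 1.25 and 1.49. Fn1 and Tgfbi belong to the matrix list, whose median lay inside the random lists on the downhill array (0.16) but stood apart under 4 alternatives (0.23 to 0.68). In the interferon list, Rsad2 was the extreme member on both running arrays, at -0.64 on the downhill array, where 21 of 32 members were higher, and at 2.71 on the uphill array, where 22 of 32 were lower.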
